A study of Mus musculus with 7 samples.

How the data were processed

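Droplet 3' single-cell RNA libraries of total hindlimb muscle, homeostatic MuSCs, injured MuSCs and primary myoblasts were used, 7 in all. The values were deposited as raw UMI counts per gene and cell barcode for 27998 genes, as whole numbers with no normalization per the file headers. The submitters' processing notes name bcl2fastq 2.17.1, Cell Ranger 2.2.0, Seurat 2.3.4 and the mouse build mm10, without the role or order of each tool. Groups were taken from the labels, with 2 libraries each for total muscle, homeostatic MuSCs and injured MuSCs and 1 for primary myoblasts. Libraries of different groups share a replicate number and nothing else that would pair them. The comparisons, tests, gene lists, cell type markers, rule for named genes and the other settings, except those named as later, were chosen before the data were examined.

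Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were used, which left out 13 and 8 barcodes of total muscle 1 and 2, 55 and 37 of homeostatic MuSC 1 and 2, 39 and 40 of injured MuSC 1 and 2 and 15 of primary myoblasts. Scrublet, run per library, called 64 of 15267 cells doublets (0.419%). A doublet rate of 0.8% for every 1000 cells recovered in a library would give more, 322 (2.11%). Scrublet's calls lay below the number at that rate in each library except injured MuSC 1, with 14 called against 13. These calls were left out as planned, and leaving out the 322 cells with the highest scores was added as an alternative. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave clusters in scanpy 1.11.5 and leidenalg 0.10.2. A cluster was named, with the ending "-like", after the marker list with most members among its top 10 genes against the other cells of total muscle, or else with the largest share of its markers raised, if at least 3 markers were raised, and was left unnamed where epithelial genes led. Near-identical copies of a gene are other genes that match the last 300 bases of a transcript over at least 90 bases at 95% identity (blastn 2.17.0, GENCODE M21 transcripts, 27645 of 27998 genes searched, 4932 with a copy). That annotation release may not be the one used for the deposited counts.

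Counts of myogenic-like cells were summed per library. They came to 322381 and 442439 UMIs in total muscle 1 and 2, 3288049 and 2919946 in homeostatic MuSC 1 and 2, 8725529 and 6542303 in injured MuSC 1 and 2 and 112800964 in primary myoblasts. The sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05), whose standard error is the log2 fold change divided by the root of F. The injury and sort comparisons used 2 libraries against 2. Those of primary myoblasts used the 5 sorted and cultured libraries in 1 fit, in which the single myoblast library is assumed to vary like the sorted groups. Biological coefficients of variation were 11.6%, 12.8%, 11.7% and 11.7%. Gene lists (22) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. With so few libraries the form with an estimated correlation has little power, so a list that it does not call is left undecided by it. Folds against a group without counts are lower bounds at 3 counts over the group, and folds against 1 to 3 counts are ratios with their counting interval. CPM values of a comparison are scaled within it.

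Named genes are every tested myogenic transcription factor, the 8 genes with the largest rise and the 8 with the largest fall of at least 50 CPM that moved the same way in all libraries, and up to 4 passing members of each list of at least 30 CPM, or else its 2 most abundant members as values. Symbols of predicted genes and markers of other cell types were left out of the largest changes. The same choice was repeated among autosomal genes without a copy. Members called against the direction of a called list, called members of lists with 5 or fewer, and the mitochondrially encoded genes without a copy after injury, were chosen after their values were seen. Some genes that the rule names are not reported here. The text gives a subset of the genes that the rule names for the largest changes and for the lists. For splits and ligands the 4 members with the highest mean CPM were taken.

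The share of cells with a Top2a or Mki67 UMI was computed after thinning each cell to 1000 UMIs, leaving out shallower cells. The same share in the cells outside the myogenic class, and without shared barcodes, was added after seeing the data. Splits are k-means with 2 parts on principal components (scikit-learn 1.9.0), computed per group without the genes of the lists compared and without mitochondrial and ribosomal protein genes, and list medians were set against 10000 random lists of like expression. Further tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. On simulated counts with 200 changed genes, the edgeR test recovered 75.3% of 2-fold and 100% of 4-fold changes in the injury design, 30.9% and 84.6% in the sort design, 73.7% and 97.0% for myoblasts against injured and 57.9% and 92.9% for myoblasts against homeostatic MuSCs. False calls were 6.59%, 1.84%, 4.05% and 2.00% of the calls. The simulation changed only these 200 genes, in both directions alike, with a single dispersion for all genes and libraries. In the data 75.0%, 7.70%, 60.15% and 71.6% of the tested genes passed. The simulated rates thus do not cover scaling under changes as broad as those. For myoblasts they also take for granted that the single library varies like the sorted groups.

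Results were recomputed with DESeq2's Wald test and size factors, no low count filter, stricter cell filters (500 genes, 5% mitochondrial), doublet calls ignored, Leiden resolutions of 0.5 and 2, all cells in place of the myogenic class, all 7 libraries in 1 fit, counts thinned to the smallest library, the replicate number as a block, other thinning depths (500, 2000), 3 parts in the splits, and leaving out each library in turn. Chosen after seeing the data were no scaling beyond library size, autosomal genes without a copy, barcodes with at least 9 G or C bases, leaving out the cells with the highest doublet scores, leaving out barcodes shared by the injured libraries, and the smallest against the largest of 3 parts. Splits of the samples into other groups were not counted, since no group has 3 libraries.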

Results

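Single-cell RNA sequencing with a droplet 3' kit was carried out on 7 mouse libraries in 4 groups. Total muscle (2 libraries) holds live cells sorted from enzymatically dissociated hindlimb muscle of mice 3 months old. Homeostatic muscle stem cells (MuSCs, also called satellite cells; 2 libraries) were sorted from muscle for which the labels name no injury. Injured MuSCs (2 libraries) were sorted 60 h after injury with 2 µM notexin, a snake venom phospholipase that destroys myofibres. Primary myoblasts (1 library) were satellite cells grown on collagen for 4 to 5 passages with 2.5 ng/µl bFGF and 10% horse serum. The values are counts of unique molecular identifiers (UMIs) per gene and cell barcode. Total muscle 1 and 2 hold 7853341 and 9835824 UMIs in 1982 and 2432 barcodes, with a median of 3055.5 and 3204 UMIs per barcode before filtering. Homeostatic MuSC 1 and 2 hold 3675157 and 3319283 UMIs in 1629 and 1452 barcodes, with medians of 2245 and 2300. Injured MuSC 1 and 2 hold 9238859 and 7172165 UMIs in 1295 and 2255 barcodes, with medians of 7196 and 3111. The primary myoblast library holds 114382567 UMIs in 4429 barcodes, with a median of 24779. Intervals given for shares and ratios are 95% intervals (exact binomial for shares) and cover counting error only.

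Which cell types unsorted muscle holds was asked of the total muscle libraries. Fibro-adipogenic-like cells, the connective tissue progenitors marked by Pdgfra and Dcn, made up 29.3% ± 0.684 of the cells (SD, n = 2, as for the values that follow). Endothelial-like cells made up 17.6% ± 0.208, B-like cells 16.2% ± 0.0021, T- or NK-like cells 10.2% ± 1.28 and tenocyte-like cells, marked by Tnmd, 7.62% ± 0.0378. Myogenic-like cells made up 4.86% ± 0.381. Macrophage- or monocyte-like cells reached 3.43% ± 0.119, mural-like cells 3.22% ± 0.281, mature myofibre-like cells 2.14% ± 0.427 and glial-like cells 1.14% ± 0.265. A cluster named lymphatic endothelial-like by its markers, led by the venular genes Selp and Ackr1, made up 2.82% ± 0.10. It is a mixed cluster, whose share was 1.06% with stricter cell filters and 1.12% with finer clustering. Cells of a haemoglobin cluster made up 0.113% ± 0.0156, and 1.34% ± 0.0929 stayed unnamed. No cluster was named after neutrophil or dendritic markers, and such cells within other clusters were not counted. The sort for live cells and the dissociation can set these shares.

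**Figure D1:**
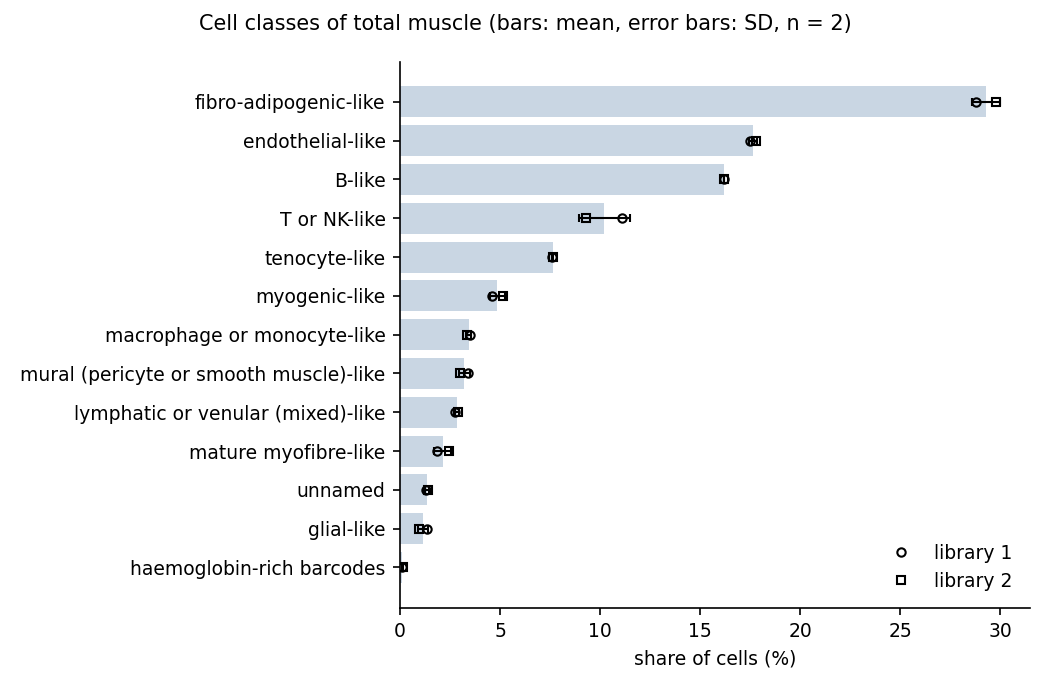
Share of each cell class in the total muscle libraries, in percent of the cells used, with points for the libraries and bars for their mean. Fibro-adipogenic-like cells are the largest class at a mean of 29.3%, and myogenic-like cells make up 4.86%.

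The share of myogenic-like cells differed between total muscle and the sorted and cultured groups. It was 4.59% (3.70 to 5.61) and 5.13% (4.28 to 6.08) in total muscle 1 and 2, and 81.7% (79.7 to 83.6) and 73.6% (71.2 to 75.8) in homeostatic MuSC 1 and 2. In injured MuSC 1 and 2 it was 92.1% (90.5 to 93.5) and 85.1% (83.6 to 86.6), and among primary myoblasts 99.3% (98.98 to 99.50). Without the barcodes that both injured libraries hold it was 96.8% (95.5 to 97.8) and 95.9% (94.97 to 96.8) in injured MuSC 1 and 2. The comparisons between groups below use the summed counts of these myogenic-like cells. Clusters 0 and 15 hold those of total muscle and homeostatic MuSCs, clusters 2, 3 and 21 those of injured MuSCs, and clusters 1, 4, 5, 7, 17 and 19 those of primary myoblasts.

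The injury comparison asks what MuSCs express 60 h after muscle damage against homeostatic MuSCs. Cell cycle genes rose: 38 of the 38 tested members of the S phase list were higher in injured MuSCs and none lower, with a median log2 fold change of 3.71. Of 51 tested genes of the G2 and M phase list, 48 rose and Hjurp, a centromere chaperone, fell (log2 -0.63 ± 0.19, SE), with a median of 5.84, or 4.99 with genes lacking counts in homeostatic cells at their bound. Cdk1, the mitotic kinase, was 750-fold higher by its counts (134 to 29630), Ccna2 (cyclin A2) 629-fold (113 to 24880), Uhrf1, which maintains DNA methylation, 757-fold (136 to 29930), and E2f8 at least 79.7-fold. Genes of differentiation and fusion rose in 16 of 19 cases, with a median of 3.93, or 3.76 at the bound. Myog, a myogenic transcription factor of differentiating cells, rose by a log2 of 7.09 ± 0.43 (182 ± 50.2 CPM in injured against 1.24 ± 1.76 in homeostatic MuSCs; SD, n = 2 each), Ttn by 6.53 ± 0.27 and Mylpf by 5.03 ± 0.39. All 9 homeostatic counts of Myog lie in homeostatic MuSC 1, and without homeostatic MuSC 2 its log2 was 6.14. The only homeostatic counts of Cdk1 and Ccna2 lie in homeostatic MuSC 2 and that of Uhrf1 in homeostatic MuSC 1. Mylpf was 4.36 without homeostatic MuSC 1 and 5.99 without homeostatic MuSC 2. The creatine kinase Ckm fell (log2 -2.23 ± 0.59), at 0.742 CPM in injured against 3.89 in homeostatic MuSCs. Counts adjusted over the list alone were the same for these lists. Camera called each of these lists up, with adjusted p = 5.49e-16 for S phase, 1.28e-22 for G2 and M phase and 1.57e-05 for differentiation. The adjusted p was 0.444 for each with an estimated correlation. Camera in that form gave an unadjusted p of 0.0753 for S phase and 0.068 for G2 and M phase, although 38 of 38 and 48 of 51 genes rose. With 2 libraries per group it can hardly pass and does not decide the question. Mature myofibre markers moved with them (4 of the tested markers higher and Ckm lower, median log2 3.75). Leaving out homeostatic MuSC 2 ended the call of Ckm (log2 -1.49), of which 2 counts are left without injured MuSC 1, and leaving out injured MuSC 2 that of Hjurp (-0.60), which was also lost among cells with GC-rich barcodes (-0.33).

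Genes linked to the resting stem cell state fell in the same comparison. Of 24 tested quiescence-associated genes 19 fell (20 adjusted over the list alone), with a median log2 of -3.00. Cdkn1b, which encodes the cell cycle inhibitor p27, rose (log2 2.58 ± 0.20), and is among the genes that depend on the base content of the cell barcode in the injured libraries (log2 2.12 with GC-rich barcodes, still called). Chrdl2, a secreted BMP antagonist, was at least 1539-fold lower, Hey1, a Notch target, fell by 4.24 ± 0.23 on the log2 scale, Notch3 fell by 3.75 ± 0.22, and the non-coding RNA Meg3 fell by 11.57 ± 0.22. Immediate early genes, which respond to stimulation and to tissue dissociation, fell in 23 of 24 cases and none rose (median -3.04). Egr1 went from 677 ± 193 to 6.97 ± 0.678 CPM (log2 -6.61 ± 0.24), and Egr2 fell by 6.52 ± 0.39. Heat shock and chaperone genes fell in 10 of 12 cases (median -2.31), with Hspa1a at 1875 ± 1518 CPM in homeostatic against 2.73 ± 1.16 in injured MuSCs (log2 -9.46 ± 0.61) and Hspa1b lower by a log2 of -7.85 ± 0.53. Hspe1 rose (log2 0.47 ± 0.16). Camera called these lists down, with adjusted p = 6.46e-10, 2.42e-12 and 3.64e-06. The adjusted p was 0.444, 0.444 and 0.466 with an estimated correlation. Of the Notch pathway 2 genes rose and 6 fell (7 adjusted over the list alone), with Notch2, which depends on the barcode as well, higher by 2.90 ± 0.22 (2.66 with GC-rich barcodes, still called), and the list was not called (camera adjusted p = 0.196). Leaving out homeostatic MuSC 1 and 2 in turn moved Hspa1a to -8.27 and -10.15 and Hspa1b to -6.96 and -8.44, and without injured MuSC 1 a single count of Egr2 is left in injured MuSCs. Marker lists of cell types fell as well: 10 of 12 myogenic markers, which share members with the lists given here, fell (median -2.03, camera adjusted p = 5.46e-05 among the marker lists). So did 4 of 5 mural markers (-3.75, 0.0247) and 4 of 4 erythroid markers (-6.93, or -5.34 at the bound; 0.0453), from libraries in which a haemoglobin cluster held 14.3% and 24.0% of the cells. With an estimated correlation the adjusted p was 0.263, 0.481 and 0.523. The call of Hspe1 ended without homeostatic MuSC 2 (log2 0.21) and without scaling (0.18).

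Extracellular matrix, interferon and antigen presentation genes fell in injured MuSCs. Of 21 matrix genes 17 fell (median -3.22). Col15a1 was at least 148-fold lower and the basement membrane collagen Col4a1 fell by 7.55 ± 0.30 on the log2 scale, while Col1a2 rose by 3.26 ± 0.22 and Lamb1 by 0.83 ± 0.30. Of 15 interferon response genes 12 fell (median -2.93), with Isg15 lower by a log2 of -3.62 ± 0.33 and Ifi35 by -2.93 ± 0.23. Bst2 (log2 0.58 ± 0.20), Rsad2 (2.98 ± 0.44) and Xaf1 (2.50 ± 0.25) rose. Of 11 genes of MHC class I presentation 9 fell (median -2.33). H2-K1 fell by 4.45 ± 0.17 and H2-D1 by 3.98 ± 0.20, each with 9 near-identical copies, while H2-T23 (1.73 ± 0.21) and the immunoproteasome gene Psmb10 (3.59 ± 0.22) rose. Counts adjusted over the list alone were the same. Camera called these lists down with adjusted p = 6.22e-07, 0.0233 and 0.0049, and with an estimated correlation the adjusted p was 0.444, 0.444 and 0.461. The interferon call was lost among cells with GC-rich barcodes (adjusted p = 0.0784) and among genes without a copy (0.0504), with a range of 0.0105 to 0.444 over the other settings. That of MHC class I was lost among genes without a copy (0.0806; range 0.000729 to 0.461). Fibro-adipogenic markers, which include matrix genes, moved the same way (7 lower, median -4.61). Since markers of other cell types fell as well, RNA from such cells was not separated here from expression in MuSCs. Col4a1 was -6.85 without injured MuSC 1 and has 3 counts left without injured MuSC 2. Rsad2 was 2.29 without homeostatic MuSC 1 and has 2 homeostatic counts left without homeostatic MuSC 2. The call of Lamb1 was lost without homeostatic MuSC 1 (log2 0.91), homeostatic MuSC 2 (0.70) or injured MuSC 1 (0.75), and that of Bst2 without homeostatic MuSC 1 (0.47) or injured MuSC 2 (0.56). Both calls were also lost by DESeq2 (adjusted p = 0.166 for Lamb1 and 0.0759 for Bst2) and without scaling (log2 0.54 and 0.29). That of Lamb1 was lost with all cells (0.65) and that of Bst2 with thinned counts (0.49).

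Metabolic genes moved as well. Nuclear-encoded oxidative phosphorylation genes rose in 67 of 71 cases and none fell (median log2 1.98), the tricarboxylic acid cycle in 14 of 19 (median 0.87; Sdhd 2.76 ± 0.19, Cs 2.54 ± 0.18) and serine and one-carbon metabolism in 11 of 13 (median 1.90). Psat1, of serine synthesis, rose by 3.69 ± 0.17 and Tyms, the thymidylate synthase, by 3.39 ± 0.23. Camera adjusted p = 5.91e-20, 0.00503 and 0.000298, and 0.444, 0.619 and 0.444 with an estimated correlation. Cytosolic ribosomal protein genes rose in 67 of 77 cases (median 0.77, adjusted p = 3.64e-06, and 0.619 with an estimated correlation), and 1 of the 77 has no near-identical copy. Of 13 mitochondrially encoded genes 9 rose (median 2.32, adjusted p = 3.01e-07, and 0.444 with an estimated correlation) and mt-Nd2 fell (log2 -0.39 ± 0.14). Among the 6 of them without a copy 3 rose, with a median of 0.50. The gene mt-Atp6, which has a copy, went from 167 ± 66.4 to 9819 ± 91.7 CPM (log2 5.87 ± 0.24), and mt-Atp8, which has none, was 507-fold higher by its counts (173 to 2459). Leaving out homeostatic MuSC 2 moved the log2 of mt-Atp8 from 8.89 to 9.49, with 1 homeostatic count left. Of the others without a copy mt-Nd6 (2.32 ± 0.20) and mt-Nd1 (0.78 ± 0.12) rose, while mt-Cytb (0.19), mt-Nd4 (0.21) and mt-Nd5 (0.09) did not pass and had the other sign without scaling (-0.10, -0.08 and -0.20). Both mt-Cytb (0.29) and mt-Nd4 (0.32) passed without injured MuSC 2 and with 7 libraries in 1 fit (0.36 and 0.38), and mt-Nd5 was -0.11 without injured MuSC 1. Glycolysis genes rose in 11 of 17 cases (median 0.78, adjusted p = 0.0424, and 0.619 with an estimated correlation). Slc2a1 (log2 -2.61 ± 0.21), Hk1 (-1.42 ± 0.25), Hk2 (-1.77 ± 0.15) and Pfkp (-2.88 ± 0.17) fell, and the median over the 7 members without a copy was -1.41. Eno3, the muscle enolase, went from 3.34 ± 0.354 to 469 ± 134 CPM (log2 7.12 ± 0.28), and Pgam1, with 3 copies, rose by 6.30 ± 0.23. Not called were fatty acid oxidation (median 0.27, adjusted p = 0.599; -0.02 without scaling), cholesterol synthesis (median -0.21 and mean 0.15, 0.851), ribosome biogenesis (-0.34, 0.291), proteasome (0.09, 0.478; -0.20 without scaling) and p53 targets (0.58, 0.165). Counts adjusted over the list alone were the same except 6 in place of 7 higher for fatty acid oxidation. The call of mt-Nd2 was lost without homeostatic MuSC 1 (log2 -0.33) or injured MuSC 2 (-0.25) and with 7 libraries in 1 fit (-0.22). The glycolysis list lost its call without homeostatic MuSC 1 (adjusted p = 0.0761) or homeostatic MuSC 2 (0.0753), and among genes without a copy its direction was down (0.476), with a range of 0.00304 to 0.619 over the other settings. Ribosome biogenesis was called down without homeostatic MuSC 1 (0.0429), and p53 targets were called up by fry (0.0343).

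The myogenic transcription factors split in direction. Among 13 tested, Myog, Six4 (log2 2.74 ± 0.26), Id2 (1.33 ± 0.14), Mef2a (0.76 ± 0.17) and Myf5 (0.54 ± 0.19) rose. Msc (log2 -5.79 ± 0.19), Myod1 (-2.60 ± 0.14), Pax3 (-2.05 ± 0.38), Pax7 (-1.87 ± 0.26), Id3 (-1.45 ± 0.15) and Mef2d (-1.10 ± 0.24) fell, and the list was not called (camera adjusted p = 0.465). Pax7, the satellite cell marker (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528 in GRCm38), had 9.62 ± 2.44 CPM in injured against 34.6 ± 11.3 in homeostatic MuSCs (adjusted p = 2.14e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in 2 of 2 libraries). Myod1 (ENSMUSG00000009471), a determination factor, had 259 ± 9.64 against 1573 ± 48.0 CPM (adjusted p = 1.25e-09 in the same edgeR test). The value of Id1 (log2 -0.14 ± 0.17) did not pass, except without scaling (-0.43). Myf5 had 308 ± 95.4 against 211.5 ± 32.9 CPM (adjusted p = 0.0217 by edgeR), and its call was lost without homeostatic MuSC 1 (log2 0.36) or injured MuSC 2 (0.21), without scaling (0.25) and among cells with GC-rich barcodes (0.29).

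**Figure D2:**
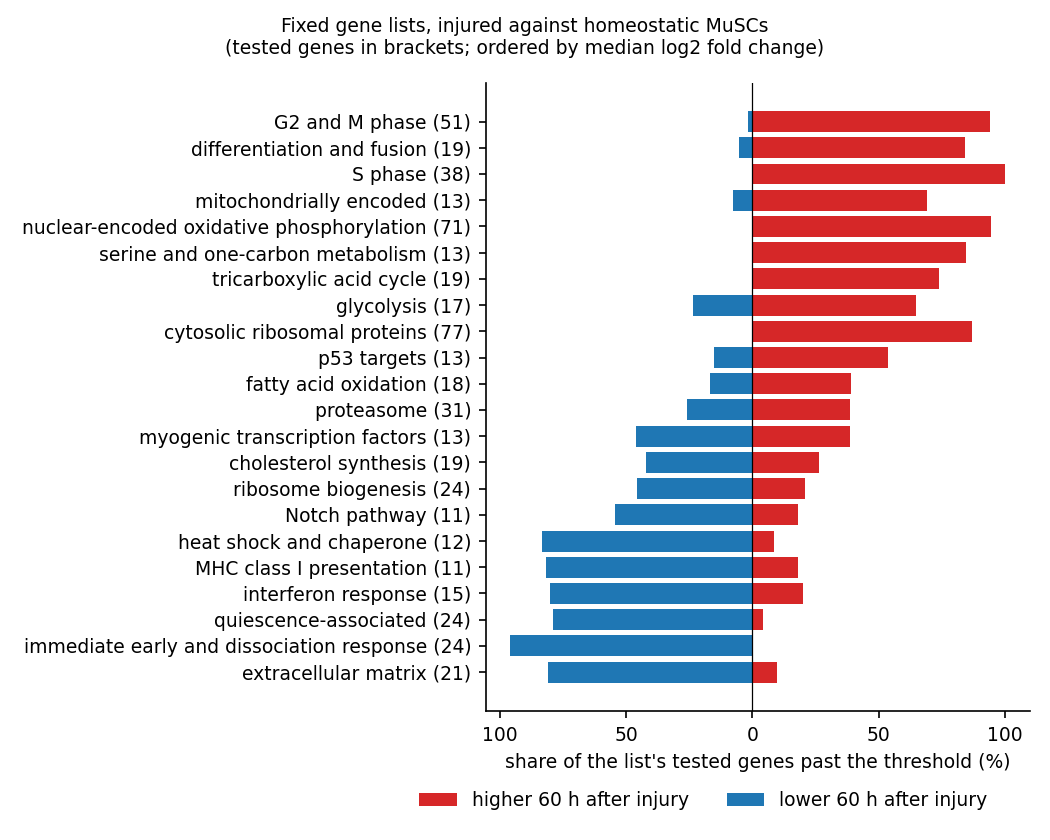
Share of the tested genes of each fixed list that passed the threshold, higher or lower in injured than in homeostatic MuSCs, in percent. Lists are ordered by their median log2 fold change, highest for G2 and M phase at 5.84 and lowest for extracellular matrix at -3.22.

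Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4061 genes higher and 3924 lower of 10648 tested, 3141 and 3060 of them by over 2-fold, with 2 libraries per group and a biological coefficient of variation of 11.6%. Without scaling the median of all genes moved from 0.027 to -0.27. Camera called 15 of 22 lists (9 up, 6 down), 0 with an estimated correlation (smallest adjusted p = 0.444, 0 at an unadjusted p under 0.05) and 16 with fry. Among genes of at least 50 CPM with the largest rises, the histone Hist1h2ap (19 copies) was at least 594.5-fold higher, mt-Nd4l (1 copy) at least 1673-fold, the cell cycle gene Cdca3 at least 277-fold, Pbk (with a copy) at least 163.5-fold, Eno1b (with a copy) at least 156.6-fold and Cst6 at least 136.7-fold. The pseudogene Rps12-ps3 (21 copies) was 4940-fold higher by its counts (1367 to 40800). Lower were Gbp2 (at least 876-fold), Tnxb (with a copy; at least 368-fold) and S1pr3 (at least 330.4-fold). The homeostatic and injured libraries differed in sex-linked transcripts: the X-inactivation RNA Xist was 2047-fold higher by its counts (700 to 9929), and the Y-linked Ddx3y 3932-fold lower (705 to 155400). Autosomal genes with a near-identical copy had a median log2 of 0.53 (878 higher and 465 lower of 1742), and those without a copy -0.08 (3031 and 3328 of 8525).

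**Figure D3:**
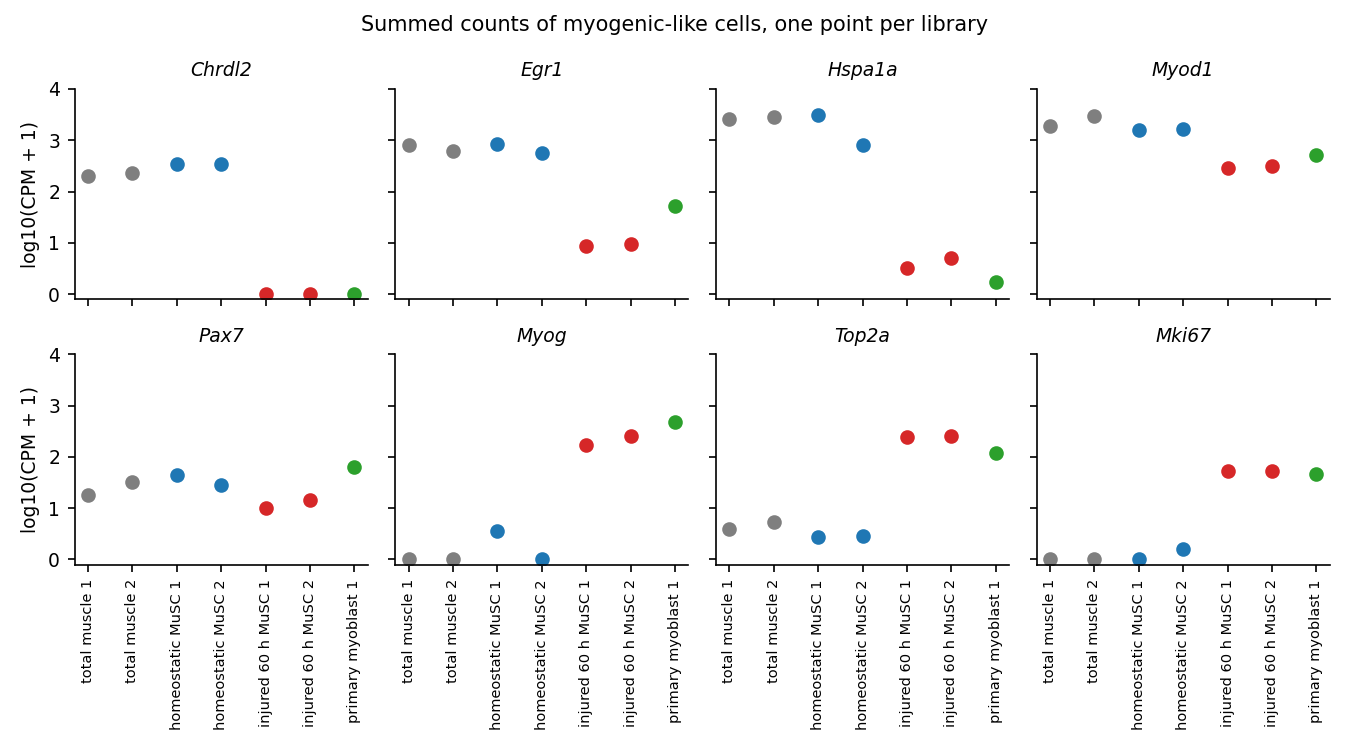
Expression of 8 genes in the myogenic-like cells of each library, as log10 of CPM plus 1. Chrdl2, Egr1 and Hspa1a lie lower, and Myog, Top2a and Mki67 higher, in both injured libraries than in both homeostatic libraries.

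Whether myogenic-like cells divide was asked with the share that had a UMI of Top2a or Mki67, a topoisomerase and an antigen of dividing cells, after thinning each cell to 1000 UMIs. The share was 19.7% ± 0.123 in injured MuSCs (SD, n = 2), with 19.8% (17.5 to 22.2) and 19.6% (17.8 to 21.5) in the libraries. It was 0.177% ± 0.107 in homeostatic MuSCs and 0.959% ± 0.215 in total muscle (n = 2 each), and 13.5% (12.5 to 14.5) in the primary myoblast library. The total muscle share rests on 1 cell with such a UMI in each library and went from 0% to 1.36% over the other settings. Endothelial-like cells of total muscle 1 and 2 had 0.292% and 0.930%, at median depths of 1968 and 2130.5 UMIs, so that the share of total muscle myogenic-like cells did not differ from that background beyond counting error. In the homeostatic libraries the haemoglobin cluster, at median depths of 653 and 685 UMIs, had 0.446% (0.0113 to 2.46) and 0.295% (0.0075 to 1.63) after thinning to 500 UMIs. Myogenic-like cells had 0.156% and 0.0962% at that depth, no higher than this background. The injured libraries hold too few cells of a type that should lack these genes. Their macrophage-like cells (25 and 19) had 8% (0.984 to 26.0) and 5.26% (0.133 to 26.0), at median depths of 2663 and 1156 UMIs. Their tenocyte-like cells had 0% (0 to 33.6) of 9 cells and 11.5% (2.45 to 30.2) of 26 cells. Unnamed cells, most of them with a barcode that both injured libraries hold, had 11.1% of 63 cells and 15.3% of 118 cells. Macrophages can divide too, and the cells of these classes are too few or too little separate to bound the part of 19.7% that free RNA gives. That part stays open. In the myoblast library 0 of the 32 cells outside the class had such a UMI, which allows a share of up to 9.38% at 3 counts, so that the background is poorly limited there. Without the barcodes that both injured libraries hold the injured share was 18.3%. Median depths of the myogenic-like cells were 3418.5 and 3391.5 in total muscle, 2495 and 2797 in homeostatic MuSCs, 7475.5 and 3281 in injured MuSCs and 24776.5 in myoblasts. Without thinning the shares were 54.7%, 0.379%, 1.36% and 50.7% in injured, homeostatic, total muscle and myoblast cells, with 65.1% and 44.3% in injured MuSC 1 and 2. Thinning left out 93 and 60 cells of the homeostatic libraries and 7 of injured MuSC 2. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.33, and no other test of the shares was run.

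**Figure D4:**
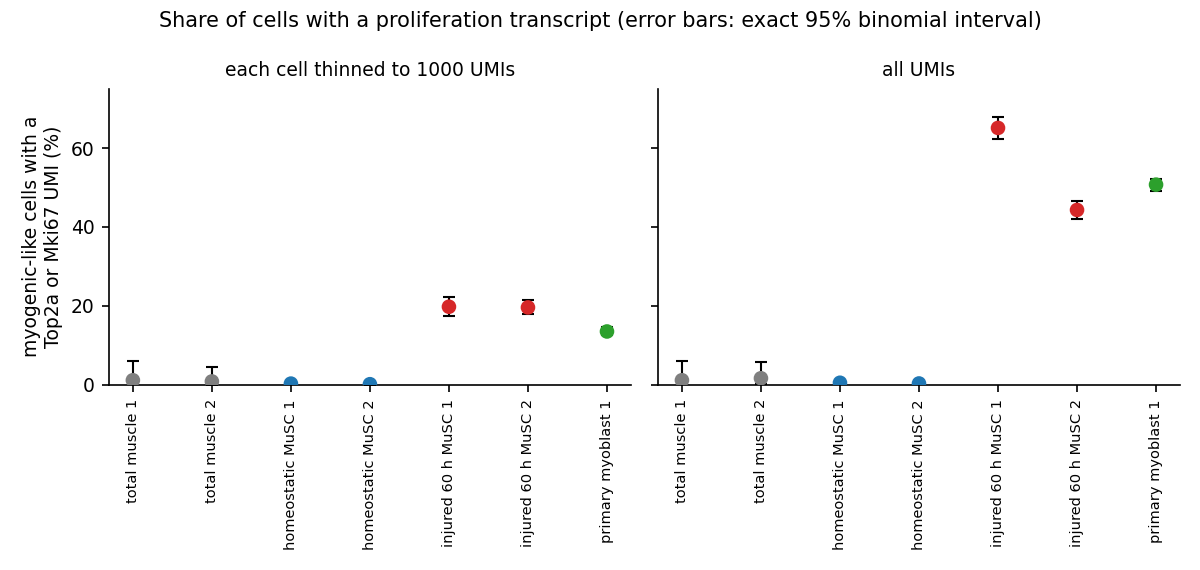
Share of myogenic-like cells with a Top2a or Mki67 UMI, in percent, with exact 95% intervals per library, after thinning to 1000 UMIs per cell and with all UMIs. After thinning both injured libraries lie near 19.7%, above the myoblast library at 13.5%. With all UMIs injured MuSC 1 (65.1%) lies above and injured MuSC 2 (44.3%) below the myoblast library (50.7%).

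Sorted homeostatic MuSCs were also set against the myogenic-like cells of total muscle, as sorted against unsorted cells of the same class. The groups also differ in sex-linked transcripts, with Xist at 0.286 and 0.634 CPM in homeostatic MuSC 1 and 2 against 713 and 622 CPM in total muscle 1 and 2, so that the sort and donor sex are not separated here. All 77 tested cytosolic ribosomal protein genes were lower in sorted cells (median log2 -0.72; Rps4x -1.11 ± 0.08, Rps6 -1.06 ± 0.08). Differentiation and fusion genes fell in 6 of 10 cases (median -3.59), with the myosin light chain Myl1 lower by a log2 of -4.54 ± 0.46, as did all 6 tested markers of mature myofibres (median -3.85), 7 of 9 fibro-adipogenic markers (median -2.54), 3 of 4 endothelial (-3.50) and 3 of 3 tenocyte markers (-2.43). Markers of other cell types fell as well, so RNA from such cells was not separated here from expression in myogenic-like cells. Myogenic markers rose in 4 of 11 cases (6 adjusted over the list alone; median 0.58, camera adjusted p = 0.00837 among the marker lists, and 0.18 with an estimated correlation). Quiescence-associated genes rose in 8 of 24 cases (median 0.50; Itm2a 1.90 ± 0.19), while the Notch target Hes1 fell (log2 -1.75 ± 0.47), and 9 of 11 mitochondrially encoded genes rose (median 0.75; mt-Atp6, with a copy, 2.10 ± 0.33). Of MHC class I genes H2-D1 (log2 0.82 ± 0.12), H2-K1 (0.73 ± 0.16) and Tap1 (2.202 ± 0.592) rose (median 0.74). Of ribosome biogenesis the nucleolar Npm1 (-0.92 ± 0.14) and Nhp2 (-0.58 ± 0.15) fell (6 adjusted over the list alone), of S phase Fen1 (-1.67 ± 0.48; 0 adjusted over the list alone) and of the proteasome Psmd8 (-0.62 ± 0.16), with medians of -0.29, -0.36 and -0.25. Other counts of called lists were the same adjusted over the list alone. Camera adjusted p = 1.97e-68 for ribosomal proteins, 1.2e-16 for differentiation, 5.39e-06 for quiescence, 1.32e-10 for mitochondrial genes, 0.0167 for MHC class I, 0.000308 for ribosome biogenesis, 0.0342 for S phase and 0.0199 for the proteasome. With an estimated correlation the adjusted p was 0.487, 0.269, 0.558, 0.558, 0.558, 0.937, 0.558 and 0.937. Of 11 other settings, 4 called S phase (adjusted p of 0.0194 to 0.783), 6 the proteasome (0.00366 to 0.937), 6 MHC class I (0.000853 to 0.558) and 8 ribosome biogenesis (8.2e-07 to 0.937). These counts include all cells in place of the class, where the proteasome, MHC class I, ribosome biogenesis and ribosomal proteins were called in the opposite direction. The S phase call was lost without homeostatic MuSC 2 (0.0586) or total muscle 1 (0.193), with the replicate block (0.0537), with GC-rich barcodes (0.308), with all cells and by fry (0.177). The proteasome call was lost without homeostatic MuSC 1 (0.393) or total muscle 1 (0.0607), that of MHC class I without homeostatic MuSC 2 (0.225) and that of ribosome biogenesis without homeostatic MuSC 1 (0.146). Fry called ribosomal proteins and differentiation (0.0259 each).

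Among myogenic transcription factors Msc rose in sorted cells (log2 0.85 ± 0.16), Myod1 (-0.67 ± 0.14) and Id3 (-0.62 ± 0.11) fell, and Pax7 (0.41), Pax3 (0.09), Myf5 (0.01), Mef2a (-0.21), Mef2d (0.98), Id1 (-0.23) and Id2 (-0.0018) did not pass. Genes with large rises were Mgarp (log2 2.93 ± 0.41), Igfbp5 (2.75 ± 0.29) and Loxl2 (3.005 ± 0.49, 73 copies), and the Y-linked Ddx3y was at least 75.4-fold and Eif2s3y at least 17.2-fold higher. Xist was 1544-fold lower by its counts (525.5 to 7510), H2-Ab1 at least 123-fold, Cd74 209.5-fold (68.9 to 1039) and Ifi27l2a 181-fold (47.0 to 1542). In all, 318 genes were higher and 290 lower of 7895 tested (7.70% passed; 52.3% of calls higher, and 63.1% without scaling), 230 and 133 by over 2-fold, from 90 and 124 myogenic-like cells in the total muscle libraries. Without total muscle 2 the number lower was 191. Camera called 8 of 22 lists (3 up, 5 down), 0 with an estimated correlation (2 at an unadjusted p under 0.05) and fry 2. Medians of lists not called were -0.13 for immediate early genes, -0.0081 for heat shock, 0.01 for transcription factors, -0.23 for G2 and M phase, -0.04 for glycolysis, -0.09 for the tricarboxylic acid cycle (mean 0.04), -0.08 for oxidative phosphorylation, 0.18 for fatty acid oxidation, -0.07 for serine metabolism, 0.20 for cholesterol synthesis, 0.16 for Notch, 0.40 for matrix (with camera's direction down), 0.81 for interferon and 0.08 for p53 targets (mean -0.08). Calls were lost without total muscle 2 for Myod1 (log2 -0.33), H2-K1 (0.50), Hes1 (-0.84), Nhp2 (-0.47), Psmd8 (-0.49), Fen1 (-1.91) and Tap1 (2.95, with 1 count left in total muscle). They were lost without homeostatic MuSC 1 for Nhp2 (-0.40), Psmd8 (-0.59) and Fen1 (-1.50). Without homeostatic MuSC 2 they were lost for Hes1 (-1.05), Psmd8 (-0.59) and Fen1 (-1.82), while Mef2d passed (1.33). Without total muscle 1 they were lost for Tap1 (1.85) and Fen1 (-1.44). Hes1 was -3.04 without homeostatic MuSC 1. Loxl2, with 6 counts in total muscle, was 2.05 without total muscle 2 and has 1 count left there without total muscle 1. The 2 homeostatic counts of Ifi27l2a lie in homeostatic MuSC 2. DESeq2 did not call Hes1 (adjusted p = 0.499), Fen1 (0.138), Tap1 (0.166), Nhp2 (0.0655) and Psmd8 (0.0506). With GC-rich barcodes Hes1 (log2 -0.02), Msc (0.91), Id3 (-0.36), Nhp2 (-0.59), Psmd8 (-0.66) and Tap1 (1.955) were not called. Further losses were Nhp2 without scaling (-0.49), Psmd8 thinned (-0.50), Fen1 with doublet calls ignored (-1.64), Hes1 without the highest doublet scores (-1.74) and Loxl2 with all cells (0.095). The list of immediate early genes was called down without homeostatic MuSC 1 (adjusted p = 0.00578) or total muscle 2 (0.00808), and heat shock without homeostatic MuSC 1 (0.00448).

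Primary myoblasts were compared with injured MuSCs, as cells dividing in culture against cells activated in muscle. Differentiation and fusion genes were higher in myoblasts in 22 of 23 cases and none lower (median log2 3.51), with the cardiac actin Actc1 at 7.17 ± 0.30 and the calcium store protein Casq2 at 6.25 ± 0.40. All 6 tested mature myofibre markers (median 3.53, camera adjusted p = 0.00237 among the marker lists) and 4 of 5 mural markers (4.52, 0.00836) were higher, and with an estimated correlation the adjusted p was 0.634 for both. Actc1 was 6.45 without injured MuSC 1 and 8.24 without injured MuSC 2. S phase genes were lower in 21 of 38 cases and none higher (median -0.69, and 0.02 with 13 higher and 12 lower without scaling), with Slbp at -4.25 ± 0.23 and Ccne2 at -3.36 ± 0.23. G2 and M phase genes were lower in 25 of 51 and higher in 7 (median -0.60, and 0.11 without scaling; Hmgb2 -3.84 ± 0.22, Cks2 -2.14 ± 0.20). Oxidative phosphorylation genes were lower in 42 of 71 and higher in 7 (8 adjusted over the list alone; median -0.49, and 0.22 without scaling) and ribosome biogenesis in 11 of 24 (median -0.39, and 0.32 without scaling). Of ribosomal protein genes 69 of 77 were lower (70 adjusted over the list alone; median -0.72, and -0.0070 without scaling), of mitochondrially encoded genes 12 of 13 (-3.51) and of MHC class I genes 7 of 11 (8 adjusted over the list alone; -0.89), with Tap1 higher (2.68 ± 0.44; not called with thinned counts, at 1.71, and with 2 counts left in injured MuSCs without injured MuSC 1). The 6 mitochondrially encoded genes without a near-identical copy were all lower, with a median of -1.12. Autosomal genes with a copy had a median of -0.38, and those without one 0.30. Camera adjusted p = 8.66e-11 for differentiation, 6.86e-06 for S phase, 0.000588 for G2 and M phase, 1.04e-05 for oxidative phosphorylation, 0.013 for ribosome biogenesis, 2.52e-14 for ribosomal proteins, 1.13e-08 for mitochondrial genes and 0.0367 for MHC class I. With an estimated correlation the adjusted p was 0.942 for ribosome biogenesis and 0.841 for the others.

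Among the transcription factors Mef2c (log2 4.77 ± 0.26), Pax7 (2.47 ± 0.25), Pax3 (2.18 ± 0.34), Myog (1.14 ± 0.23), Myod1 (0.73 ± 0.16) and Id3 (0.45 ± 0.18) were higher in myoblasts than in injured MuSCs. Msc (-6.53 ± 0.39), Myf5 (-5.45 ± 0.29), Id2 (-1.58 ± 0.19) and Six4 (-0.80 ± 0.22) were lower, and Myf6 (0.26), Mef2a (-0.32), Mef2d (-0.12) and Id1 (-0.39) did not pass. The BMP antagonist Grem1 was at least 322-fold, Gzmd at least 320.2-fold and Nefl at least 245-fold higher, and the fibronectin gene Fn1 rose by 3.91 ± 0.27, while Col1a2 (-6.26 ± 0.29), Fosb (-3.85 ± 0.29), Fos (-3.38 ± 0.32), Xist (-15.03 ± 0.43) and Rps12-ps3 (-15.69 ± 0.39) fell and mt-Nd4l was at least 40660-fold lower. The fit called 4215 genes higher and 3224 lower of 12367 (56.7% of calls higher, 81.1% without scaling and 38.8% by DESeq2's Wald test). Without scaling the median of all genes moved from 0.19 to 0.90. Lists not called had medians of -0.52 for quiescence, -0.46 for immediate early genes, -0.08 for heat shock, 0.26 for transcription factors (mean -0.15), 0.82 for glycolysis, 0.28 for the tricarboxylic acid cycle, 0.57 for fatty acid oxidation, -0.16 for serine metabolism (mean 0.35), 0.49 for cholesterol synthesis (mean -0.12), 0.37 for the proteasome, -0.72 for Notch, 0.52 for matrix (0.47 at the bound), -0.19 for interferon (mean 0.03) and 0.78 for p53 targets. Of these, quiescence (0.17), immediate early genes (0.25), heat shock (0.63), serine metabolism (0.55) and interferon (0.52) had the other sign without scaling. With 1 myoblast library, the test assumes that it varies like the sorted groups. Without injured MuSC 2 the calls of Id3 (0.32) and Six4 (-0.67) were lost and that of Id1 (-0.61) gained, as it was without homeostatic MuSC 2 (-0.39). With the replicate block the call of Id3 was lost (0.33, adjusted p = 0.149 by edgeR) and that of Id1 gained (-0.54, 0.0282). The call of Id3 was also lost by DESeq2 (adjusted p = 0.219), with its size factors (0.139), with thinned counts (0.121) and among genes without a copy (0.237), and that of Six4 without scaling (log2 -0.09). With DESeq2's size factors and among genes without a copy Id1 (-0.53 and -0.58) and Mef2a (-0.46 and -0.50) passed. Fn1 was 4.55 without injured MuSC 2. These groups also differ in the sex-linked Xist. DESeq2's Wald test did not call Myog (0.99, adjusted p = 0.692) and Grem1 (adjusted p = 0.117).

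Against homeostatic MuSCs, primary myoblasts had higher cell cycle and differentiation genes and lower quiescence and stress genes. Differentiation genes were higher in 22 of 23 cases (median log2 7.71, or 6.47 at the bound), as were all 6 tested mature myofibre markers (5.64, camera adjusted p = 0.00131 among the marker lists, and 0.226 with an estimated correlation), S phase genes in 34 of 38 (2.61; Pcna and Slbp lower) and G2 and M phase genes in 46 of 51 (5.66, or 5.04 at the bound; Rangap1, Lbr and G2e3 lower). The troponin Tnnt2 was at least 587-fold, Actc1 at least 536.5-fold, the embryonic myosin Myh3 at least 263-fold and the mast cell protease gene Mcpt8 at least 830.2-fold higher. Quiescence-associated genes were lower in 19 of 24 cases (median -3.56; Pax7, Hes1, Cdh15 and Peg3 higher), with Chrdl2 lower 55120-fold by its counts (9883 to 2178000). Immediate early genes were lower in 23 of 24 (-3.52; Klf2 higher), heat shock genes in 10 of 12 (11 adjusted over the list alone; -3.01; Hspa1b -11.65 ± 0.60), interferon genes in 14 of 15 (-3.06) and MHC class I genes in 10 of 11 (-3.28; H2-K1 -5.70 ± 0.25, Psmb10 higher). The chemokine genes Cxcl3 and Cxcl5 were at least 17060- and 9810-fold lower. Matrix genes were lower in 16 of 21 (-2.64; Fn1, Lamb1, Sparc and Tnc higher), as were all 8 tested fibro-adipogenic markers, which include matrix genes (-5.74, camera adjusted p = 5.59e-05, and 0.226 with an estimated correlation), Notch pathway genes in 9 of 13 (-1.08; Hes1, Dll1, Jag2 and Lfng higher), mitochondrially encoded genes in 11 of 13 (-1.17, and -0.92 over the 6 without a copy) and ribosome biogenesis in 16 of 24 (-1.16; Npm1 and Bop1 higher). Camera adjusted p = 3.06e-11 for differentiation, 2.98e-08 for S phase, 1.95e-12 for G2 and M phase, 6.2e-07 for quiescence, 3.27e-10 for immediate early genes, 7.5e-05 for heat shock, 3e-05 for interferon, 0.000102 for MHC class I, 0.000411 for matrix and for mitochondrial genes, 0.0225 for Notch and 0.00126 for ribosome biogenesis. With an estimated correlation the adjusted p was 0.62 for ribosome biogenesis and 0.449 for the others. Of other marker lists 4 of 4 erythroid (-12.6, or -11.4 at the bound; adjusted p = 0.00875) and 8 of 12 myogenic markers (-2.65, 0.0061) were lower, with 0.485 and 0.226 for an estimated correlation. Leaving out homeostatic MuSC 1 and 2 in turn moved Hes1 to 2.63 and 0.66. Without homeostatic MuSC 1 Klf2 was 1.77, Hspa1b was -10.73 and 2 homeostatic counts of Dll1 and 0 of Lfng are left. Calls were lost without homeostatic MuSC 2 for Pax7 (log2 0.32) and Dll1 (0.68), also for Lfng, and without homeostatic MuSC 1 for Npm1 (0.43). DESeq2 did not call Hes1 (adjusted p = 0.356), Lfng (0.295), Cdh15 (0.0741), Npm1 (0.0644) and Dll1 (0.0566), and with thinned counts Hes1 (0.113), Cdh15 (0.125), Npm1 (0.0779), Dll1 (0.0702) and G2e3 (0.122) were not called. Without scaling and without the low count filter G2e3 (0.234 and 0.0693) and Rangap1 (0.237 and 0.0653) were not called, with the replicate block G2e3 (0.0662) and Lfng (0.178), and with all cells Klf2 (0.209), Dll1 (0.0548) and Lfng (0.566). Lfng was also lost with DESeq2's size factors (0.0583) and without the highest doublet scores (0.0517).

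Metabolic lists were higher in myoblasts than in homeostatic MuSCs. Serine metabolism genes were higher in 12 of 14 cases (median 2.33; Phgdh 4.59 ± 0.21), glycolysis in 13 of 17 (1.64; Slc2a1, Hk2, Pfkp and Pgam1 lower), the tricarboxylic acid cycle in 16 of 19 (1.48), oxidative phosphorylation in 62 of 71 (1.27; Ndufb4, Cycs and Atp5l lower), fatty acid oxidation in 10 of 18 (0.61; Acadvl and Etfa lower), the proteasome in 21 of 31 (0.55; Psma3 and Psmd11 lower) and p53 targets in 8 of 13 (1.84; Phlda3 5.27 ± 0.23, Pmaip1 and Aen lower). Camera adjusted p = 0.000119, 0.00756, 0.000162, 2.54e-10, 0.0431, 0.00872 and 0.0262, and with an estimated correlation 0.449, 0.502, 0.48, 0.449, 0.616, 0.702 and 0.449. Not called were cholesterol synthesis (median -0.54, mean 0.05), transcription factors (0.13, mean -0.15) and ribosomal proteins (-0.05, and 0.36 without scaling). Among the factors, Myog (8.26 ± 0.38), Mef2c (5.74 ± 0.33), Six4 (1.96 ± 0.29), Pax7 (0.61 ± 0.24, adjusted p = 0.0245 by edgeR) and Mef2a (0.46 ± 0.20) were higher and Msc (-12.31 ± 0.36), Myf5 (-4.90 ± 0.28), Myod1 (-1.85 ± 0.18), Mef2d (-1.20 ± 0.25), Id3 (-0.99 ± 0.19) and Id1 (-0.51 ± 0.20) lower, while Pax3 (0.13), Myf6 (1.71) and Id2 (-0.23) did not pass. In all 4855 genes were higher and 4000 lower of 12367 (54.8% of calls higher, and 65.7% without scaling, which moved the median of all genes from 0.19 to 0.59). Counts of lists called were the same adjusted over the list alone except where given, and 7 transcription factors were higher by that count. Without homeostatic MuSC 2 Myog was 7.34. Calls were lost without homeostatic MuSC 1 for Mef2a (0.32), Id1 (-0.40) and Pgam1 (-0.53) and without homeostatic MuSC 2 for Pax7 (0.32), Atp5l (-0.41) and Psma3 (-0.43). Myf6 passed without homeostatic MuSC 1 (log2 9.44, against 1.71 in the main fit), injured MuSC 1 (1.73) or injured MuSC 2 (1.74). It also passed with 7 libraries in 1 fit (1.88), without the low count filter (1.92) and without scaling (2.11). The call of Pax7 was also lost by DESeq2 (adjusted p = 0.281), with its size factors (0.0857), among genes without a copy (0.0705) and with thinned counts (0.429). That of Mef2a was also lost by DESeq2 (adjusted p = 0.293), with its size factors (0.166), among genes without a copy (0.104), with thinned counts (0.317), GC-rich barcodes (0.135) and all cells (0.0642), and without barcodes shared by the injured libraries (0.0568). That of Id1 ended with 7 libraries (adjusted p = 0.103), without the filter (0.232) and without scaling (0.642). Without scaling the calls of Acadvl, Atp5l, Cycs, Psma3 and Pgam1 ended as well. Psma3 was also lost with 7 libraries, all cells and no filter, and Pgam1 with these, with GC-rich barcodes and with thinned counts.

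Whether the cells of a sort fall into parts was asked with a k-means split into 2 parts, computed without the genes of the lists compared. Cells are not replicates, so no test is made. In homeostatic MuSCs the smaller part, 21.7% and 16.6% of the cells of libraries 1 and 2, had more of the stress transcripts. The median log2 ratio of the larger to the smaller part was -2.04 and -1.92 for heat shock genes, -1.38 and -0.84 for immediate early genes and -0.55 and -0.41 for quiescence-associated genes, each at percentile 0 of 10000 random lists of like expression. Related genes outside the lists stayed in the split and lead its smaller part, such as Dnaja4 (mean log2 -3.23), Hspa4l (-2.06), Nr4a2 (-2.03) and Nr4a3 (-1.79). The low percentiles of the stress lists can thus follow from the split itself and are not a separate test. Hspa1a had 486 and 220 CPM in the larger and 13700 and 4445 CPM in the smaller part, and Fos 280 and 164 against 2527 and 1327 CPM. The 4 most abundant quiescence-associated genes did not follow their list median. Sdc4 (log2 0.94 and 0.80), Vcam1 (0.60 and 0.32) and Pdlim4 (0.19 and 0.11) were higher in the larger part, and Meg3 (-0.16 and -0.25) was slightly lower. Of these, Sdc4 is among the genes that depend on the base content of the cell barcode. Median depths were 2555.5 and 2857 UMIs in the larger and 2344.5 and 2555 in the smaller part. Transcription factors had -0.18 and -0.04 (percentiles 2.94 and 24.2), and the 3 differentiation genes with enough counts -0.21 and -0.43 (percentiles 16.75 and 4.25). With 3 parts the mean ratio of the largest to the next part was 0.046 for quiescence and 0.10 for immediate early genes, so that these directions depend on the number of parts, while that of the largest to the smallest part was -0.56 and -1.46. In injured MuSCs the parts, with 38.7% and 39.1% of the cells in the smaller one, differed in the base content of their cell barcodes. The mean number of G and C bases was 7.12 in the smaller against 8.55 in the larger part in library 1 and 7.16 against 8.75 in library 2. The mean log2 ratios of the smaller to the larger part were -0.10 for quiescence, transcription factors and differentiation, -0.11 for S phase and -0.14 for G2 and M phase. Against random lists of like expression the percentiles in libraries 1 and 2 were 88.55 and 32.3 for quiescence, 62.1 and 63.7 for transcription factors, 11.9 and 97.97 for differentiation, 94.2 and 21.3 for S phase and 19.55 and 54.5 for G2 and M phase. Only that of differentiation in library 2 lay outside the central 95% of random lists.

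**Figure D5:**
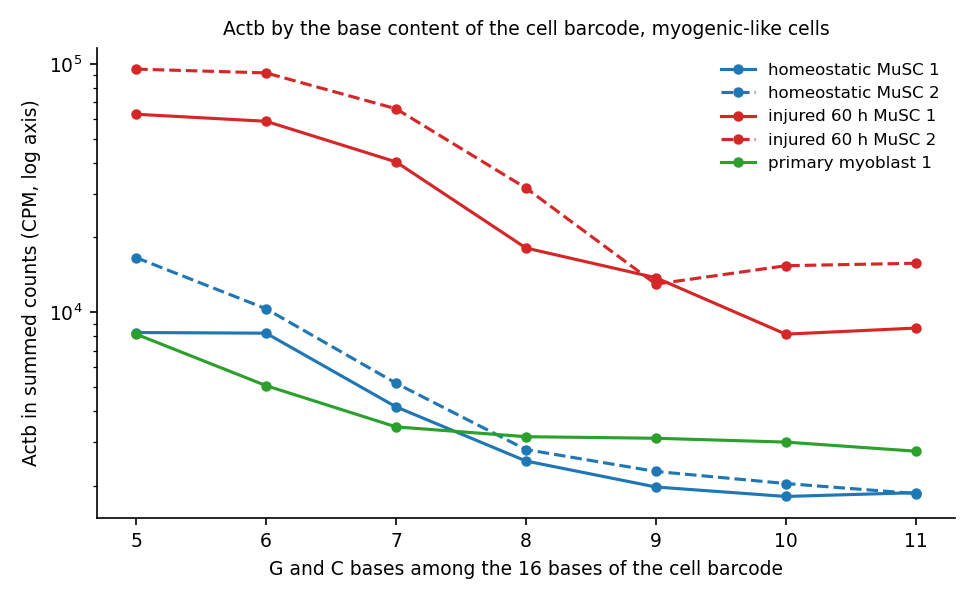
CPM of Actb against the number of G and C bases in the cell barcode, per library. In injured MuSC 1 it goes from 62662 at 5 bases to 8631 at 11 bases.

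Which cells of unsorted muscle hold transcripts of stem cell niche ligands was read from CPM per class. Of 30 ligands 28 had at least 20 counts. Fibro-adipogenic-like cells held the highest CPM for 9 of them (7 in both libraries), endothelial-like for 5 (4), mural-like for 4 (3), the lymphatic or venular cluster for 3 (3), tenocyte-like for 3 (2) and macrophage-like cells for 2 (1), and myogenic-like cells for 0. These include Hgf in macrophage-like cells (3.79 CPM, 3 counts) and Rspo3 in the lymphatic or venular cluster (9.48 CPM, 5 counts). Both lay below the level of 3 counts in the shallower library of the class (8.02 and 12.4 CPM). With stricter cell filters the lymphatic or venular cluster held 4 (0 in both libraries), endothelial-like cells 6 (4), mural-like cells 4 (4), macrophage-like cells 1 (1) and B-like cells 0, from 1. Of the 4 ligands with the highest mean CPM, the cytokine gene Il6 was highest in the lymphatic or venular cluster at 2579 ± 111 CPM (SD, n = 2), followed by mural-like cells at 1899, and was at 31.9 CPM in that class with stricter cell filters. The chemokine gene Cxcl12 was highest in mural-like cells at 1093 ± 188 CPM, with 556 in endothelial-like cells. Tgfb1 had 519 CPM in B-like cells, and Fn1 572.5 ± 12.7 CPM in tenocyte-like and 570 ± 49.8 CPM in fibro-adipogenic-like cells. No test was made on these values.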

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

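The tests of near-identical copies, RNA from other cells, dividing cells, donor sex and distinct cell states were chosen only after the result was seen, and the tests of transcript ends and of copies in the barcode pattern before.

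Genes with near-identical copies were higher in injured MuSCs. Autosomal genes with a copy had a median log2 fold change higher by 0.615 than those without, as reads shared between copies and counted differently in the injured libraries would give. The contrast did not hold for each mitochondrial gene: mt-Atp8 (8.89) and mt-Nd6 (2.32), without a copy, rose, and mt-Nd2 (-0.39), with a copy, fell. RNA from other cells would bring all abundant mitochondrial transcripts, and those without a copy had a median of 0.496. Among them mt-Cytb (0.19), mt-Nd1 (0.78) and mt-Nd4 (0.21), the most abundant of them in homeostatic MuSCs, lay far below mt-Atp6 (5.87), which has a copy. A state of dividing cells would raise the same transcripts in primary myoblasts, where mt-Atp6 was lower than in homeostatic MuSCs by a log2 of -5.48. The higher of the fitted values of both genes was -3.42 for Rps12-ps3, from 4 counts in myoblasts and 2 in homeostatic MuSCs, a 12.0-fold lower ratio with a counting interval of 1.09 to 83.8. A difference in how the reads of the injured libraries were aligned or counted is a candidate explanation that may account for part of the rises of these genes, and what that difference was stays open, as does the rise of mt-Atp8 and mt-Nd6.

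The homeostatic and injured libraries differed in sex-linked transcripts. Xist had 0.286 and 0.634 CPM in homeostatic MuSC 1 and 2, 896 and 1236 in injured MuSC 1 and 2 and 713 and 622 in total muscle 1 and 2, and Ddx3y 321 and 264, 0.148 and 0, and 0 and 0. If donor sex were the cause of the autosomal calls of the injury comparison, they would be lost against the myogenic-like cells of total muscle, which have Xist like the injured libraries. The check covers 6880 autosomal calls, fewer than all those of the injury comparison. Of them 69.7% were called the same way there and 25 the opposite way. The sign was the same for 95.8%, against 57.4% in data simulated with no effect, where both comparisons share the injured libraries. Both also share how the reads of those libraries were counted, so the agreement does not separate injury from a difference in counting. An effect of sex on some of the genes stays open, since sex differs with the group. The sort comparison and that of myoblasts (Ddx3y at 37.1 and Xist at 0.0282 CPM) with injured MuSCs differ in the same transcripts, and an effect of sex on them was not tested.

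In the injured libraries 51 of 1169 genes were over 2-fold higher in cells whose barcode holds few G and C bases, among them Actb, Myf5, Cdkn1b (log2 1.82 and 1.77) and Notch2 (2.80 and 2.39), a signal in the barcode sequences that no comparison uses. Distinct states of the cells would leave the parts of the injured split alike in their barcodes, but their mean number of G and C bases differed by at least 1.44. Genes of the pattern such as Abhd2, Pam and Clasp2 were not left out of that split and led its smaller part. The difference can thus follow from the pattern itself. It shows that the parts track the barcode and is not a separate test of cell states. Loss of molecules that join a barcode and a transcript end both rich in G and C would need ends richer in G and C in these genes, whose median over the last 300 bases was lower by 4.17 points than in the other genes (difference -4.17). Near-identical copies would be common among them, and 27.5% have one against 44.5% of the other genes. The cause stays open, and the same genes had a median log2 of 0.98 and 1.16 in the homeostatic, 1.51 and 1.09 in the total muscle and 0.53 in the myoblast libraries. The total muscle values rest on 10 cells with few such bases against 19 with many in library 1, and 21 against 15 in library 2. There 129 and 115 genes were over 2-fold higher, against 127 and 126 with the cells shuffled.

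A haemoglobin cluster, outside the myogenic class, held 14.3% of the cells of homeostatic MuSC 1 and 24.0% of homeostatic MuSC 2 (224 and 339 cells), against 0.102% and 0.124% in total muscle and 0% in injured MuSCs and primary myoblasts. A cluster of 56 cells of total muscle, left unnamed since epithelial genes led it, was headed by the keratin genes Krt18 and Krt8 with Cldn4 and Epcam. The injured libraries shared 253 barcodes, against at most 16 and a mean of 6.4 for the other pairs of libraries, and the profiles behind a shared barcode had a median correlation across genes of 0.284 against -0.0054 for other pairs of cells. For 94.1% of the 253 the cell of the same barcode was the best match. In 186 pairs the cell of injured MuSC 2 had 0.0798 times the UMIs of its partner (interquartile range 0.0778 to 0.0824; medians of 863 and 10932.5 UMIs), and in the other 67 a median of 1.09 times. Of the shared barcodes 182 were in the myogenic class of injured MuSC 1 and 2 in that of injured MuSC 2, while 63 of 63 and 245 of 264 unnamed cells of these libraries were shared. The injured libraries are thus not separate in these barcodes, without which 4036 genes were higher and 3873 lower after injury.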

How the results depend on the processing

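Settings without scaling, with copy-free genes, with GC-rich barcodes, without the highest doublet scores, without shared barcodes and of the smallest against the largest part are tests chosen only after the result was seen. Of 3762 values of 194 named genes under the alternatives, 3569 kept direction and side of the threshold, 122 lost and 25 gained the call and 46 changed sign. Of 407 other values 308 stayed within their limits, 87 moved and 12 changed sign. Injury counts stayed between 3231 and 4631 higher and 3045 and 4602 lower in all 20 alternatives. The cause was not tested except where the setting itself tests fewer genes or cells. The median of all genes moved to 0.20 and 0.32 with 7 libraries (injury, and myoblasts against homeostatic MuSCs), 0.28 with all cells (sort) and 0.0455 and 0.0381 with DESeq2's size factors (myoblasts against injured and homeostatic MuSCs). Depth limits the sort comparison, which rests on 90 and 124 cells of total muscle.

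With the replicate block the calls went from 7985 to 7900 for injury and from 608 to 827 for the sort, and in myoblasts against injured MuSCs Myf6 was -0.25, Id3 lost its call (0.33) and Id1 gained one (-0.54). Differences between replicates of the same number correlated at -0.0823 and 0.0988. These values give no clear sign of a pairing by number and, without an interval, do not exclude one.

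An estimated correlation called 0 lists after injury and 0 in the sort, where fry called 2 and copy-free genes and GC-rich barcodes 5 each. Genes higher in the sort were 157 with DESeq2, 507 without filter, 3551 with all cells and 106 with GC-rich barcodes. Genes lower were 4290 with all cells, 170 copy-free and 132 with GC-rich barcodes, and 191 to 285 leaving out a library. Genes higher in myoblasts than in injured MuSCs were 1774 with DESeq2, 2273 thinned and 7316 without scaling (1700 lower), and 3155 were higher than in homeostatic MuSCs with DESeq2.

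With all cells, sort values were 3.91 for Myod1, 0.23 for Id1, 0.24 for Id3, -1.22 for Igfbp5, 0.43 for Npm1, 1.21 for Nhp2, 0.33 for Rps4x, 0.22 for Rps6, -0.65 for H2-D1, -0.37 for H2-K1, 0.39 for Psmd8 and -1.09 for Tap1, since these hold other cell types. Sort values of Id2 were 0.00032 at resolution 2, 0.077 with 7 libraries, 0.0051 with strict filters, 0.086 with GC-rich barcodes, 0.064 without filter, 0.084 without scaling, 0.0056 thinned, 0.0013 without the highest doublet scores and -0.096 to 0.11 leaving out a library. Those of Myf5 were -0.0087 with DESeq2, -0.0095 with its size factors, -0.020 copy-free, -0.025 with doublet calls ignored and -0.11 to 0.17 leaving out a library. After injury Id1 was 0.037 with 7 libraries and -0.39 to 0.10 leaving out a library. All cells gave -0.014 for mt-Cytb and -0.052 for mt-Nd5, no scaling -0.10 for mt-Cytb, -0.084 for mt-Nd4 and -0.20 for mt-Nd5, and mt-Nd5 was -0.11 to 0.30 leaving out a library. Without scaling, myoblasts against injured MuSCs gave 0.32 for Id1, 0.39 for Mef2a and 0.60 for Mef2d (0.050 without filter), and against homeostatic MuSCs 0.17 for Id2. In myoblasts against injured MuSCs Myf6 ranged from -0.11 to 0.93 leaving out a library. Pax3 against homeostatic MuSCs was -0.018 with DESeq2, -0.020 with its size factors and -0.45 thinned.

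Cycling shares in percent were 0.403 at 500 UMIs, 1.36 unthinned, 0.568 with doublet calls ignored, 0.555 with all cells, 0.403 without the highest doublet scores and 0 with GC-rich barcodes in total muscle, and 0.379 unthinned, 0.343 with all cells and 0 with GC-rich barcodes in homeostatic MuSCs. In injured MuSCs they were 10.4 at 500, 33.3 at 2000, 54.7 unthinned, 19.1 with doublet calls ignored, 18.1 with all cells, 18.99 without the highest scores, 18.28 without shared barcodes and 19.3 with GC-rich barcodes. In myoblasts they were 8.44, 21.8 and 50.7 at these depths and 15.15 with GC-rich barcodes. Class shares with strict filters were 7.66 for tenocyte-like, 19.4 for endothelial-like, 1.055 for lymphatic, 16.2 for B-like and 0.0256 for haemoglobin cells. At resolution 2 they were 17.85 for endothelial-like, 1.12 for lymphatic, 4.70 for mural-like, 0.0669 for haemoglobin and 1.945 for unnamed cells, and at 0.5 1.74 for glial-like and 0.0875 for haemoglobin cells. With doublet calls ignored they were 16.1 for B-like, 0.287 for haemoglobin and 1.94 for unnamed cells, and without the highest scores 3.285, 16.3, 0.0889 and 1.17 for macrophage-like, B-like, haemoglobin and unnamed cells. Il6 in the lymphatic cluster was 31.9 with strict filters.

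In the homeostatic split, 3 parts gave 0.046 for quiescence, 0.10 for immediate early genes, -0.37 for heat shock, 0.14 for transcription factors and -0.49 for differentiation, and the smallest part -2.10 for heat shock and -0.34 for transcription factors. GC-rich barcodes gave -0.66 for quiescence, -2.09 for heat shock, -0.38 for transcription factors and -0.10 for differentiation. Heat shock was -1.57 thinned and -2.10 with doublet calls ignored. Leaving out a library gave -0.62 to -0.33, -1.43 to -0.69, -2.085 to -1.50 and -0.32 to 0.099 for the 4 lists named first. In the injured split thinning gave 0.14 for quiescence, -0.15 for transcription factors, -0.22 for differentiation and -0.21 for G2 and M phase, the smallest of 3 parts 0.26, 0.19, 3.15 and -1.275, and -0.84 for S phase, and GC-rich barcodes 0.093, -0.28, 0.026, -0.19 and -0.19. Leaving out a library gave -0.14 to 0.0062 for quiescence, -0.12 to -0.031 for transcription factors, -0.20 to 0.041 for differentiation and -0.17 to -0.13 for G2 and M phase, which was -0.11 without shared barcodes.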

Other observations

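The values of the smallest of 3 parts come from a test chosen only after the result was seen. Among injured MuSCs, the smallest of 3 parts held 3.41% and 5.34% of the cells of libraries 1 and 2 (39 and 100 cells). Against the largest part its median log2 ratio was 3.15 for differentiation and fusion genes, -0.84 for S phase and -1.275 for G2 and M phase genes. No test was made, since cells are not replicates.

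Among the 10 genes that lead in the smaller part of the homeostatic split are Dnaja4, Cxcl10, Irf1, Hspa4l and Nr4a2, and among the 10 of the larger part Cxcl3, Cxcl5, Cxcl2, Cd3eap, Nhp2 and Mrto4. They were picked for their difference between parts computed from such genes, so that their lead follows from the split, and no programme was tested with them. Sdc4, a surface proteoglycan of satellite cells, had 4978 and 5654 CPM in the larger against 2587 and 3237 CPM in the smaller part of libraries 1 and 2. Sdc4 is a member of the quiescence-associated list, whose median went the other way. It is also among the genes that depend on the barcode, with log2 1.69 and 1.81 between cells with few and many G and C bases in homeostatic MuSC 1 and 2. The mean number of these bases was 8.11 in the larger and 8.05 in the smaller part of library 1. In library 2 it was 8.08 and 8.22.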
